A study of Homo sapiens with 4 samples.

How the data were processed

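RNA was extracted with a phenol-based reagent and sequenced as Illumina libraries, per the labels' protocols. The series lists 4 samples of human C42 cells, of which the table used here covers 2, si-NC and si-ALYREF, with 1 library each. The other 2 samples, an ALYREF immunoprecipitation and its control, have no file here and were not used here. The submitters' processing notes name Bowtie 0.12.2 and the genome builds mm8 and mm9, which are mouse builds, while the labels and the gene symbols are human. The notes do not say what each was used for. The read counter, gene annotation, strand setting and filters are not given in the sources used here.

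The deposited table gives, per gene symbol, an expression value for each library, a p-value and a log2 fold change. The header names no unit for the expression values. They were read as RPKM made by the authors (reads scaled by gene length and library size) because of what they equal, as follows. The log2 fold change column was deposited by the authors per the file headers, and the p-value column likewise, with neither the test nor the assumed spread between replicates stated. Solving each gene's ratio of values together with its deposited log2 fold change, with a prior of 0.125 reads, gave whole numbers of reads in both libraries for 100% of 12968 genes (tolerance 0.01). Divided by these reads, the values equalled 1 over the exon-union length in GENCODE release 29 for 11179 of 12313 genes compared (90.8%, relative tolerance 0.0001). This length merges all annotated exons of a gene and can exceed that of any 1 transcript. The effective library sizes that the values imply were 45800000 for si-NC and 37900000 for si-ALYREF, a ratio of 1.21. Whether these are reads or read pairs is not stated. For 849 genes with over 5000 reads in both libraries, the p-values in the authors' deposited table correspond to an assumed spread between replicates of 10.1% (range 10.0% to 10.2%), so they do not rest on measured replicates.

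Of 13149 rows, 22 held a date in place of a gene symbol, a known effect of spreadsheet software. These rows stayed in the totals and were not named. A further 178 rows had no fold change and p-value. For 12482 rows the symbol as listed matched a single gene of GENCODE release 29 (GRCh38), from which lengths, positions and overlaps were taken. Older symbols were used only to match the gene lists to the rows. In this annotation 3369 listed genes share exon bases with another listed gene, and reads in shared parts cannot be assigned with the strand setting unknown.

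The solved reads over listed genes totalled 35598585 for si-NC and 31099461 for si-ALYREF. The sums of RPKM were 220392 and 216090. Genes entered had a median of 1044 reads in the library where they had fewer, with a 5th percentile of 159. A limit of 3 reads in a gene of 1 kb corresponds to 0.0654 RPKM in si-NC and 0.0792 RPKM in si-ALYREF. Intervals of ratios are 95% exact (Clopper-Pearson) binomial intervals of the solved reads, rescaled by the library sizes, and cover counting error only. PCR copies are not independent molecules, so the true error is wider.

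Log2 ratios of si-ALYREF over si-NC were computed from the deposited RPKM with a pseudocount of 1, for 10838 genes with a mean of at least 1 RPKM. Fold limits of 2 and 1.5 refer to this scale, which understates the differences of low genes, while ratios printed beside an interval are ratios of the RPKM themselves. With 1 library per group no test across samples was possible and no p-value was computed. The deposited scaling was used as the main one. The 32 gene lists were fixed before the data were examined, and cover mRNA export, 5-methylcytosine, androgen response, prostate and neuroendocrine genes, cell cycle, stress, metabolic, inflammatory, splicing, ribosomal and histone genes, and 4 sets of markers of other cell types. For each list with at least 3 members entered, the median log2 ratio was placed among the medians of 10000 random lists of equal size matched on mean expression in 20 bins. A list was taken to stand apart below the 2.5th or above the 97.5th percentile. This describes the pair of libraries and is not a test of the conditions, since genes of a list are not independent.

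The rule for named genes was also fixed before the data were examined. It takes ALYREF, the 12 highest and 12 lowest log2 ratios among 5932 genes with a symbol and a mean of at least 5 RPKM, and from each list the 3 members with the largest absolute log2 ratio, or 4 where the list stood apart. Some genes that the rule takes are not reported here. Any other gene named is said to have been chosen after its values were seen.

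The alternatives fixed before the data were examined were a scaling that sets the median log2 ratio to 0, a pseudocount of 0.1, no minimum and a mean of at least 5 RPKM, fold limits of 1.5 and 4, removal of histone, mitochondrial and ribosomal protein genes before scaling, 10 expression bins, no matching, and the mean of a list. Added after the data were seen were the solved reads in place of RPKM, scaling by total reads and removal of genes with overlapping exons. Matching on exon-union length and removal of hypoxia list genes from the glycolysis list were also added then. The scripts were tested on simulated data for the comparison of si-ALYREF with si-NC. Simulated reads were drawn around the solved si-NC reads of each gene, with counting error only and random transcript lengths. Reads were recovered exactly for 99.9% of 12968 simulated genes, and the simulated library size ratio of 1.3 was recovered. Of 100 simulated lists of 30 genes each, 5 without a shift and 90 with a log2 shift of 0.3 fell outside the central range. Those lists held independent normal values in place of reads and were placed among fewer random lists than the real ones. Of 159 simulated genes with a 3-fold difference that entered, 83.6% passed 2-fold relative to the median gene, and 0% of unchanged genes did. No spread between cultures was simulated, so this 0% does not tell how many unchanged genes pass 2-fold between real cultures. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.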

Results

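RNA sequencing was compared between 2 libraries from human C42 cells, 1 treated with a control small interfering RNA (si-NC) and 1 with a small interfering RNA against ALYREF (si-ALYREF). C42 is a name used for a prostate cancer line derived from LNCaP cells, although the labels do not spell the line out. ALYREF is an adaptor protein that binds mRNA during transcription and hands it to the nuclear export machinery, and it also reads 5-methylcytosine in mRNA. The comparison addressed which transcripts differ in abundance when ALYREF is targeted. Each condition had 1 library, so no difference below has a replicate check, and the intervals given cover counting error only. The table listed 13149 genes, and the reads behind its values came to 35598585 in the si-NC library and 31099461 in the si-ALYREF library. The series also holds 2 RNA immunoprecipitation samples, which were not analysed here.

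ALYREF itself was measured first. Its level was 43.1 RPKM in the si-NC library and 36.2 RPKM in the si-ALYREF library. That is 84.0% of the control level (95% exact interval 79.5% to 88.8%, from 3109 and 2158 reads), or a log2 ratio of −0.24. With the median gene set to no difference the level was 77.8% of the control, and with scaling by total reads it was 79.5%. The ratio lay at the 15.8th percentile of all genes entered, so the targeted gene was not among the most strongly lowered. In the authors' deposited table the p-value of ALYREF was 0.229. The gene (ENSG00000183684.7) lies on the minus strand of chromosome 17 from 81887844 to 81891586 in GRCh38, and 3.94% of its exon bases are shared with its neighbour ANAPC11.

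Among 10838 genes with a mean of at least 1 RPKM, 221 were at least 2-fold higher and 108 at least 2-fold lower in the si-ALYREF library. Among genes with a mean of at least 5 RPKM, the highest was NPPC, the precursor of C-type natriuretic peptide (ENSG00000163273.3, chromosome 2, 231921820 to 231926403), at 4.42 RPKM against 75.5 RPKM, a ratio of 17.1 (95% exact interval 14.9 to 19.7). The acute-phase plasma protein gene ORM1 was at 1.16 against 18.6 RPKM, and its close paralog ORM2 at 1.29 against 13.1 RPKM. Reads of this pair may not have been told apart by the authors' counting, so the split between them is uncertain. NNMT, which methylates nicotinamide, was at 1.08 against 11.3 RPKM, and AZGP1, a secreted zinc-binding glycoprotein, at 37.3 against 201 RPKM. FASN, the fatty acid synthase, was at 98.4 against 364 RPKM, and NPC1, which moves cholesterol out of lysosomes, at 7.19 against 30.6 RPKM. The kinase gene HIPK2 was at 15.3 against 58.3 RPKM and the autophagy gene TP53INP2 at 5.74 against 27.4 RPKM. SIPA1L2, a regulator of Rap GTPases, was at 4.54 against 24.4 RPKM, and BICD1, a dynein adaptor, at 2.51 against 12.3 RPKM. FOXD4, at 1.51 against 9.28 RPKM, has near-identical copies in the genome and is uncertain for that reason.

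Lowest in the si-ALYREF library, by the same minimum, was ANKRD37, a hypoxia-induced gene, at 21.03 RPKM in si-NC and 4.46 RPKM in si-ALYREF. Its neighbour UFSP2, a protease for the ubiquitin-like protein UFM1, was at 17.7 against 5.67 RPKM. ANKRD37 shares 35.2% of its exon bases with UFSP2, so the levels of the pair are not independent. DDIT3, the stress-induced transcription factor CHOP, was at 101 against 27.2 RPKM, with 31.6% of its exon bases shared with neighbours that include MARS and MBD6. NUPR1, another stress-induced regulator, was at 256 against 86.8 RPKM, and HMOX1, the inducible heme oxygenase, at 9.14 against 2.62 RPKM. CCNG2, an atypical cyclin of cells leaving the cycle, was at 27.3 against 8.78 RPKM. ASPH, an aspartate hydroxylase, was at 38.6 against 11.8 RPKM and the ribosome assembly gene RSL24D1 at 78.6 against 26.5 RPKM. The remaining genes of this group were 3 histone genes, HIST1H2AG, HIST1H4C and HIST2H2AB, and AC090094.1, which was at 311 against 92.7 RPKM and had no match in the annotation used. HIST2H2AB was at 1613 against 589.5 RPKM.

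**Figure D1:**
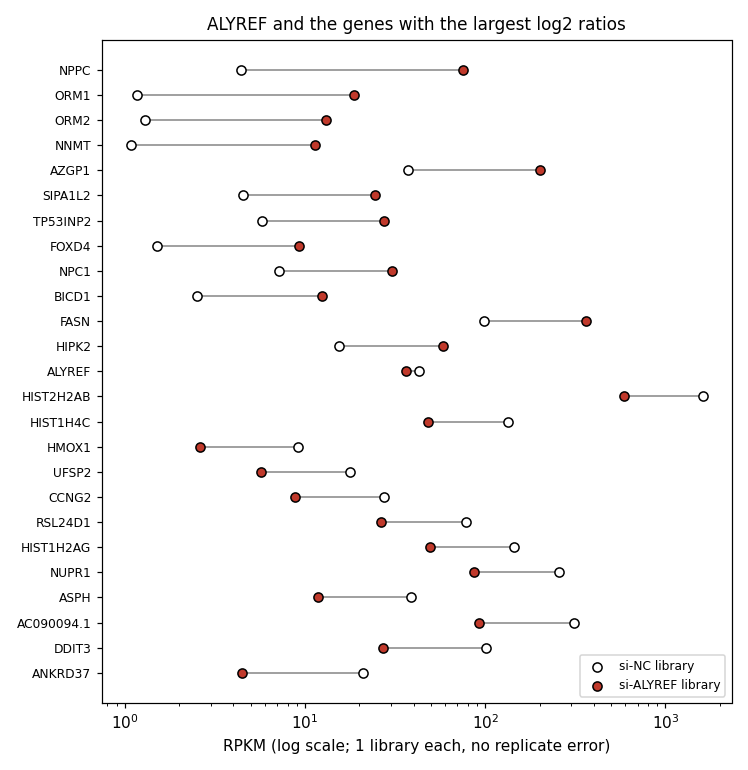
Expression of ALYREF and of the 12 genes with the highest and the 12 with the lowest log2 ratios among genes with a mean of at least 5 RPKM. The x axis is RPKM on a log scale, open dots are the si-NC library and filled dots the si-ALYREF library, 1 library each; the ALYREF dots lie close together at 43.1 and 36.2 RPKM.

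The median gene was itself 0.11 higher in the si-ALYREF library on the log2 scale, so differences are best read against that shift. As deposited, 67.2% of the genes past 2-fold were higher. With the median gene set to no difference the counts were 154 higher and 164 lower (48.4% higher), and with scaling by total reads 185 and 143 (56.4% higher). Whether more genes were higher or lower therefore cannot be read from this table. A p-value under 0.05 stood in the authors' deposited table for 4746 of 12971 genes, with 3415 higher and 1331 lower.

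Genes of lipid synthesis were higher as a group. Of 24 cholesterol synthesis and uptake genes, 17 were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 0.80 that lay above those of all 10000 random lists of similar expression. FDFT1, the squalene synthase, was at 19.8 RPKM in si-NC against 48.5 RPKM in si-ALYREF, and DHCR7, an enzyme of the last steps, at 5.56 against 13.9 RPKM. Among 15 fatty acid synthesis genes, 11 were at least 1.5-fold higher and 0 lower, and the median of 0.96 again exceeded all random lists. Beside FASN these included FADS2, a fatty acid desaturase, at 43.1 against 134.7 RPKM, ACSL1, which activates fatty acids, at 18.6 against 56.7 RPKM, and the lipogenesis gene THRSP at 2.86 against 12.6 RPKM.

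Androgen-responsive genes were also higher at the median, though not in every member. The list median was 0.49, above all random lists, with 14 of 38 genes at least 1.5-fold higher and 1 lower. FKBP5, a chaperone of steroid receptors, was at 28.8 against 95.2 RPKM, and the transcription factor gene MAF at 0.910 against 6.30 RPKM. ORM1, given above, was another member with a large ratio. KLK3, which encodes prostate-specific antigen, was at 723 against 624 RPKM and was chosen after its value was seen. The prostate lineage list stood at a median of 0.07 (44.3th percentile), with 2 of 16 members higher and 1 lower. Its sign turned to −0.04 with the median gene at no difference. Within it the epithelial cadherin gene CDH1 was at 22.4 against 48.6 RPKM, the keratin gene KRT8 at 172 against 279 RPKM and the ion channel gene TRPM8 at 3.30 against 1.14 RPKM.

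Most hypoxia-responsive genes were lower, and the median of the glycolysis list was lower. In the hypoxia list 17 of 25 genes were at least 1.5-fold lower and 0 higher, and the median of −0.74 lay below all random lists. BNIP3, a mitophagy receptor, was at 182 RPKM in si-NC against 68.9 RPKM in si-ALYREF, and P4HA1, a collagen prolyl hydroxylase, at 122 against 51.9 RPKM. The glycolytic enzyme gene PGK1, a member of both lists, was at 245 against 93.2 RPKM. VEGFA, chosen after its value was seen, went the other way at 51.4 against 73.4 RPKM. Across 23 glycolysis genes the median was −0.48, below all random lists, with 8 at least 1.5-fold lower, 15 within 1.5-fold and 0 higher. ENO1, the main enolase, was at 681 against 396.6 RPKM. PFKFB4, which controls a regulator of the pathway, was at 12.1 against 6.98 RPKM and PDK1, which diverts pyruvate from mitochondria, at 3.56 against 1.73 RPKM. Of the 23 genes 7 also stand in the hypoxia list, among them PGK1, ENO1, PFKFB4 and PDK1 and 5 of the 8 lower ones. The other 16 had a median of −0.39 (0.02th percentile), with 3 at least 1.5-fold lower.

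Transcripts of cytosolic ribosomal proteins were lower as a group. Of 78 genes, 64 were at least 1.5-fold lower and 0 higher, all 78 lay below the median gene, and the list median was −0.86. Their share of the reads was 11.3% in the si-NC library and 5.86% in the si-ALYREF library. RPS3A was at 992 against 391 RPKM, RPL34 at 485 against 192 RPKM and RPSA at 466 against 211 RPKM. Many processed pseudogenes resemble these genes, and 11.2% of the exon bases of RPS3A are shared with neighbours, so single values are uncertain. Reads shared with pseudogenes could affect the group as well, which was not tested. Replication-dependent histone genes had the lowest list median, −0.96, with 18 of 22 at least 1.5-fold lower and 0 higher. HIST1H2AG was at 145 against 49.3 RPKM, HIST1H4C at 134 against 48.1 RPKM, HIST2H2AC at 581 against 213 RPKM and HIST1H2AE at 710.3 against 279 RPKM. Both medians lay below those of all random lists, and members of the histone family are similar in sequence.

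Transcripts of the mitochondrial genome went the opposite way. All 13 measured genes were at least 1.5-fold higher, with a median of 1.44 above all random lists, and their share of the reads was 0.920% in si-NC and 2.32% in si-ALYREF. MT-ATP8 was at 231 against 839 RPKM and MT-ATP6 at 514 against 1645 RPKM, both encoding ATP synthase subunits with partly overlapping reading frames. MT-CO3, a cytochrome oxidase subunit gene, was at 725 against 2165 RPKM and MT-ND6, a complex I subunit gene, at 936 against 2742 RPKM. Nuclear genes of oxidative phosphorylation had a slightly lower median of −0.11 at the 0.11th percentile, with 3 of 45 members at least 1.5-fold lower and 0 higher. COX7C was at 871 against 428 RPKM, ATP5O at 16.3 against 10.1 RPKM and ATP5C1 at 50.6 against 33.1 RPKM. This list moved to the 3.02th percentile when genes with overlapping exons were left out. ATP5O and ATP5C1 had no match in the annotation under the symbols listed, so their exon overlap is unknown.

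**Figure D2:**
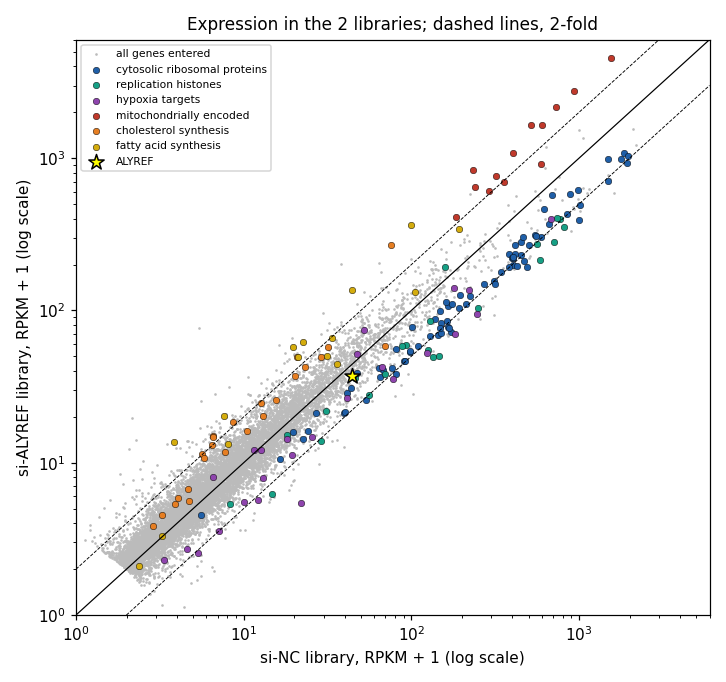
Expression of each gene entered in the 2 libraries, with RPKM plus 1 on log axes, si-NC on the x axis and si-ALYREF on the y axis. Coloured dots are members of 6 gene lists, the star is ALYREF, and the dashed lines mark 2-fold differences; the 13 mitochondrially encoded genes lie above the diagonal and the 78 ribosomal protein genes below it.

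The unfolded protein response and heat shock lists stood above random lists, and the amino acid response list lay within their range. The unfolded protein response list had a median of 0.40 (99.9th percentile), with 7 of 23 genes at least 1.5-fold higher and 0 lower. The endoplasmic reticulum chaperone gene HSPA5 was at 90.9 against 174.5 RPKM, HYOU1 at 47.0 against 91.6 RPKM, CALR at 635 against 1189.6 RPKM and EDEM1, which directs misfolded glycoproteins to degradation, at 5.11 against 8.69 RPKM. Heat shock genes had a median of 0.36 (99.5th percentile), with 6 of 21 higher and 0 lower. The inducible chaperone gene HSPA1A was at 37.0 against 83.1 RPKM and its near-identical copy HSPA1B at 69.4 against 142 RPKM, BAG3, a cochaperone, at 12.9 against 26.3 RPKM and HSPH1 at 7.91 against 15.2 RPKM. The amino acid response list was split, with 3 of 30 genes higher, 3 lower and a median of −0.02 (9.74th percentile). DDIT3 and NUPR1, given above, were the lowest of them, and AARS, a tRNA synthetase gene, was at 108.5 against 192 RPKM.

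The list medians of p53 targets and immediate early genes were lower, with most members within 1.5-fold. The p53 list median was −0.30, below all random lists, with 7 of 29 genes at least 1.5-fold lower and 1 higher. BTG2, an antiproliferative gene in both lists, was at 18.7 RPKM in si-NC against 6.58 RPKM in si-ALYREF, the cyclin gene CCNG1 at 25.8 against 11.2 RPKM and BBC3, which encodes the cell death activator PUMA, at 3.32 against 1.304 RPKM. GDF15, a stress-induced cytokine gene, was the higher member at 66.6 against 138 RPKM. Immediate early genes had a median of −0.20 (0.03th percentile), with 5 of 18 lower and 0 higher. The phosphatase genes DUSP1 and DUSP2 were at 26.9 against 11.5 RPKM and 2.62 against 0.916 RPKM, and FOS at 2.69 against 1.06 RPKM.

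Of the cell cycle lists, that of G2 and M phase stood apart from random lists and that of S phase did not, and the difference between them was not tested. Genes of G2 and M phase had a median of −0.17, below all random lists, with 8 of 53 at least 1.5-fold lower and 2 higher. HMGB2, a chromatin protein gene, was at 96.2 against 53.9 RPKM, PSRC1, a spindle protein gene, at 13.5 against 7.74 RPKM and the checkpoint kinase gene TTK at 2.59 against 1.11 RPKM. The proliferation marker MKI67 was higher, at 20.5 against 34.8 RPKM. The S phase list had a median of 0.23 (95.8th percentile), with 2 of 45 higher and 1 lower. CLSPN, a replication checkpoint gene, was at 7.88 against 13.4 RPKM, the ribonucleotide reductase gene RRM2 at 24.9 against 38.6 RPKM and the primase gene PRIM1 at 7.23 against 4.26 RPKM. With random lists matched on exon-union length as well, this list lay at the 98.5th percentile.

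The pathways in which ALYREF acts did not stand apart from other genes. For mRNA export factors the median was 0.09 (34.9th percentile), 30 of 31 genes lay within 1.5-fold, 1 was higher and 0 were lower, and the median was −0.02 with the median gene at no difference. The nucleoporin genes NUP98 and NUP153 were at 7.71 against 12.1 RPKM and 4.53 against 7.21 RPKM, and the THO complex gene THOC3 was at 36.1 against 23.9 RPKM. For genes that write, read or remove 5-methylcytosine the median was 0.19 (75.7th percentile), and all 12 genes lay within 1.5-fold. NSUN2, the main mRNA cytosine methyltransferase, was at 16.9 against 24.7 RPKM, YTHDF2, a reader of methylated mRNA, at 12.7 against 17.8 RPKM and FMR1, an RNA-binding protein gene, at 13.7 against 18.5 RPKM.

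**Figure D3:**
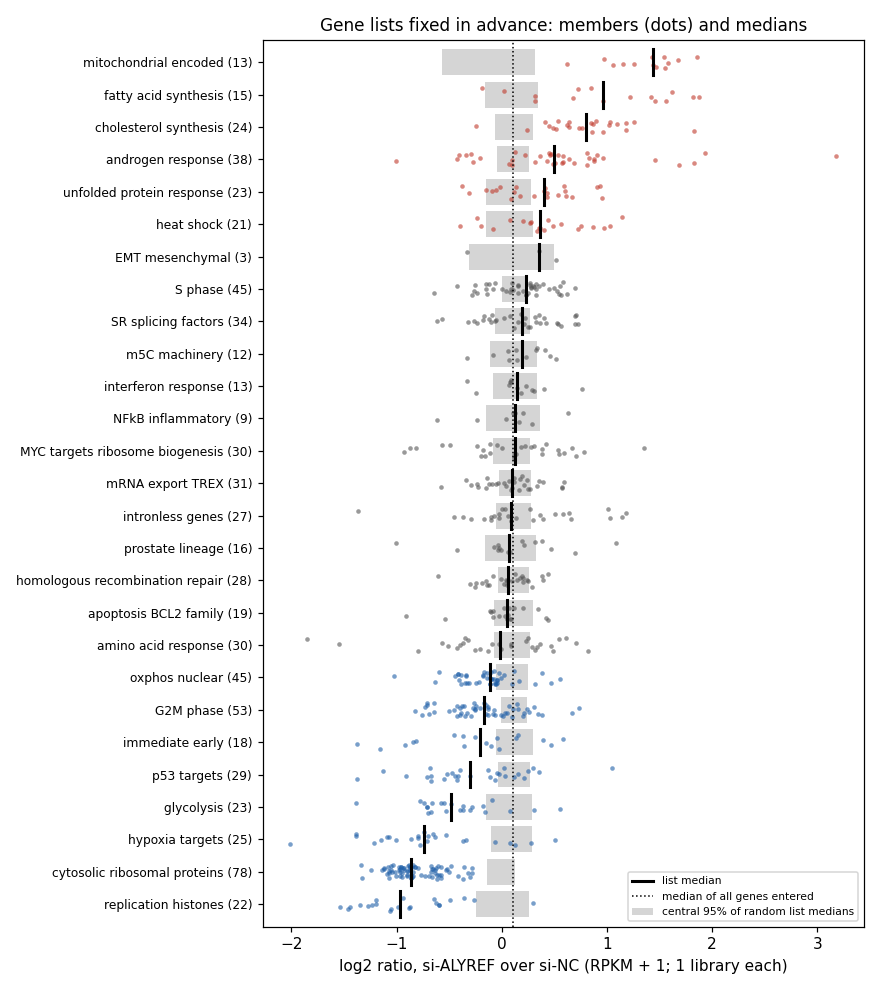
Log2 ratios of si-ALYREF over si-NC (x axis, RPKM plus 1) for the members of 27 gene lists fixed in advance, with member counts in parentheses. Dots are genes, black bars list medians, grey boxes the central 95% of medians of random lists and the dotted line the median gene at 0.11; 6 lists lie above and 8 below their boxes.

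Across all lists, 695 listed genes were entered, of which 93 (13.4%) were at least 1.5-fold higher and 134 (19.3%) at least 1.5-fold lower. Among the lower ones were 64 ribosomal protein and 18 histone genes, so these lists carry most of that share. Of all genes entered, 9.78% were higher and 4.03% lower by that limit, or 6.40% and 6.14% with the median gene at no difference, where the listed genes stood at 10.1% and 22.7%. These shares, percentiles and intervals describe a pair of libraries, and the spread between cultures of the same condition is unknown here.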

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

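Among 2135 genes with reads below the minimum of 1 RPKM, which no comparison above uses, genes were taken whose 95% exact interval of the ratio lay wholly beyond 8-fold in either direction, or which had 0 reads in si-NC and more than 3 in si-ALYREF. This limit was chosen after the values were seen, and genes with wide ratios but fewer reads or smaller differences fall short of it. Of the 6 genes that met it, 3 had reads in both libraries and were higher in si-ALYREF, and the direction of the other 3 is set by the limit itself. ADARB2, which encodes a brain-enriched relative of the RNA-editing deaminases, had 6 reads in si-NC and 387 in si-ALYREF, a ratio of RPKM of 78.1 (95% exact interval 35.6 to 214). CYP4F8, a cytochrome P450 of fatty acid and prostaglandin hydroxylation, had 4 and 159 reads, a ratio of 48.1 (18.4 to 179). MAB21L2, a developmental gene, had 8 and 141 reads, a ratio of 21.3 (10.5 to 50.4). SLC6A3, the dopamine transporter gene, had 0 reads in si-NC and 99 in si-ALYREF. Set against an assumed 3 reads in the si-NC library, that is 39.95-fold higher. Such values leave out the counting error of the si-ALYREF reads and are not interval bounds. P2RY14, a receptor for nucleotide sugars, had 0 and 44 reads, 17.8-fold higher by the same assumption. CHST9, a sulfotransferase gene, had 0 and 38 reads, 15.3-fold higher by it. The 4 genes listed at 0 in the si-ALYREF library had no fold change in the table and were not assessed. No explanation of these differences was tested.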

How the results depend on the processing

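The solved reads, total-read scaling, exon overlap, shared member and length-matching alternatives were chosen after the data were seen. No paired analysis was possible because each condition has 1 library. For the same reason replicates could not be left out. Scaling factors of count models had been foreseen for deposited counts and were not run on the solved reads, and no second unit was used. No alternative turned the direction of ALYREF, of a named gene or of a list outside the random range, but the balance of higher and lower genes turned, as given above. For the lists, 293 alternatives left a list on the same side of the percentile limits and 2 did not. The 293 include the scaling to the median gene for 27 lists, which cannot move a percentile. Scaling by total reads can move one only through the pseudocount. Neither scaling therefore tests the place of a list. In the 2 that changed side, nuclear oxidative phosphorylation moved to the 3.02th percentile without genes whose exons overlap. S phase moved to the 98.5th percentile with length matching, and the cause was not tested in either. At a mean of at least 5 RPKM, 25 of the 27 lists kept at least 3 members. The list medians of mRNA export, prostate lineage, homologous recombination, intronless and BCL2 family genes changed sign with the median gene at 0, all inside the random range. Counts past 2-fold depended on low genes and scaling. Higher genes numbered 404 with a pseudocount of 0.1, 433 from solved reads and 135 with histone, mitochondrial and ribosomal protein genes left out before scaling, against 221. Lower genes numbered 164 with the median gene at 0, 165 with a pseudocount of 0.1 and 182 from solved reads, against 108. A 1.5-fold limit gave 1060 higher and 437 lower, and a 4-fold limit 9 and 1, by construction. The log2 ratio of ALYREF was −0.36 with the median gene at 0. The share of listed genes higher was 10.1% with the median gene at 0, 16.3% with a pseudocount of 0.1, 16.8% at a mean of at least 5 RPKM, 16.7% from solved reads and 5.18% with a 2-fold limit. The share lower was 22.7% with the median gene at 0, 22.8% at a mean of at least 5 RPKM and 6.19% with a 2-fold limit. Of 330 alternatives for 110 named genes, 181 stayed within counting error and 149 moved by more. Counting error is wider for genes with fewer reads, while the missing replicates limit every result.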

Other observations

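Several lists not described above did not stand apart from random lists. For SR proteins and other splicing factors the median was 0.19 (85.8th percentile). The percentile was 33.5 with random lists matched on exon-union length too. Of the 34 genes, 4 were at least 1.5-fold higher and 1 lower. Among them HNRNPD was at 27.0 RPKM in si-NC against 45.4 RPKM in si-ALYREF, HNRNPM at 66.0 against 108.5 RPKM and SRSF4 at 13.0 against 21.7 RPKM. MYC targets and ribosome biogenesis genes went both ways, with 5 of 30 higher, 3 lower and a median of 0.12 (62.4th percentile). The transferrin receptor gene TFRC was at 12.8 against 34.3 RPKM, while the nucleolar genes NPM1 and GNL3 were at 1117 against 587 RPKM and 73.9 against 39.9 RPKM. The list of genes without introns, which need export without splicing, had a median of 0.09 (36.2th percentile), with 6 of 27 higher and 1 lower. The list was not checked against the annotation, in which its member CLDN4 holds introns, with 4702 exon bases between 73799542 and 73832693 on chromosome 7. Its percentile ran from 29.7 to 92.3 over the alternatives, the highest being without a minimum, so its place among random lists is loosely set. The tight junction gene CLDN4 was at 11.3 against 26.9 RPKM and the transcription factor gene SOX4 at 35.2 against 13.0 RPKM, and HSPA1A, given above, was the remaining gene the naming rule took from this list, in which 4 genes were at least 2-fold higher and 1 lower. Homologous recombination genes had a median of 0.06 (22.8th percentile), with 0 of 28 higher and 1 lower. BARD1 was at 18.9 against 12.1 RPKM and XRCC2 at 1.57 against 2.49 RPKM. The BCL2 family had a median of 0.05 (25.0th percentile), with 0 of 19 higher and 1 lower. Its lower member was BBC3, and beside it BID was at 5.94 against 3.77 RPKM and BCL2L1 at 21.6 against 29.7 RPKM.

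Immune and differentiation genes were few. Interferon-responsive genes had a median of 0.14 (60.4th percentile), with 1 of 13 higher and 0 lower, and IRF7 was at 2.04 against 4.16 RPKM, ISG15 at 38.8 against 51.6 RPKM and USP18 at 13.8 against 10.7 RPKM. Inflammatory genes under NF-κB had a median of 0.13 (56.8th percentile), with 1 of 9 higher and 1 lower. There NFKB2 was at 15.05 against 23.8 RPKM, LIF at 1.63 against 0.719 RPKM and RELB at 0.862 against 1.27 RPKM. Mesenchymal genes had 3 members entered, 0 of them past 1.5-fold, with a median of 0.36 (90.3th percentile). TAGLN was at 1.197 against 2.14 RPKM, FN1 at 3.56 against 4.84 RPKM and VIM at 1.47 against 0.968 RPKM. Of the neuroendocrine list 2 genes entered, ENO2 at 28.7 against 20.2 RPKM and EZH2 at 9.16 against 13.4 RPKM. Among markers of other cell types, 0 fibroblast, endothelial and hepatocyte genes entered, and of the immune markers only the lysosomal gene CD68 did, at 6.17 against 14.9 RPKM.

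In the paragraphs that follow, the scaling, counting-error, culture, siRNA, sample label and length-trend tests were chosen after the results were seen. The list of TOP mRNAs was made after the ribosomal protein result was seen and before the values of the list as a group were computed.

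The lower ribosomal protein and histone transcripts were weighed against technical explanations. With 1 library per siRNA, the bootstrap intervals here and below can only reflect the spread among the genes of a list. Those genes are not independent, and the spread between cultures is not covered. A first correction subtracted the median of other genes in the same decile of exon-union length. The ribosomal protein median was then −0.93 (95% bootstrap interval −1.003 to −0.82) and the histone median −0.93 (−1.17 to −0.62). By GC content the same correction gave −1 for ribosomal proteins (−1.05 to −0.93) and −1.15 for histones (−1.36 to −0.78), which argues against length bias and GC content bias as the whole cause. Library scaling shifts all genes alike, here by at most 0.15. Apart from the pseudocount it therefore cannot change the 0.97 and 1.07 by which the medians lay below the median gene. That holds by construction and was not a test. A hypothesis is that mRNAs with a terminal oligopyrimidine (TOP) start were lower together, and the 25 entered TOP mRNAs of a list without ribosomal proteins had a median of −0.48, with 11 at least 1.5-fold lower, 0 higher and all 25 below the median gene, at percentile 0.04 of random lists, or 0 when the pool held no ribosomal protein genes. Differences in RNA selection, reads shared with pseudogenes and differences in growth between the cultures were not tested and may contribute.

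The lower hypoxia-responsive transcripts kept a median of −0.85 (95% bootstrap interval −1.06 to −0.70) after the length correction and of −0.85 (−0.98 to −0.65) after the GC content correction, against −0.74 before. Library scaling shifts all genes alike, here by at most 0.15. By construction it leaves the 0.85 by which the list lay below the median gene, apart from the pseudocount, so this was not a test. A difference in culture state between the 2 dishes, such as density or oxygen, could lower such genes, and so could the siRNA against ALYREF. These cannot be told apart with 1 library per siRNA.

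ALYREF was only slightly lower in the si-ALYREF library. Counting error alone does not account for this under the deposited scaling. The interval, 79.5% to 88.8% of the control, holds neither an equal nor a halved level. It leaves out the spread between cultures, which is unknown, so neither level is excluded for the conditions themselves. Reads of another gene overlapping ALYREF exons are unlikely to hide a larger difference, as 3.94% of the exon bases are shared. A wrong sample label stays open, because 1 library per siRNA leaves no second library to compare. The header of the si-ALYREF values also carries a number, absent from the si-NC header, whose meaning the labels do not give. Those values were assigned to the only sample labelled si-ALYREF. Recovery of the transcript by the time of harvest and a partial transfection were not tested, so the differences in this text describe the labelled libraries and cannot be assigned to loss of ALYREF.

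Genes with a greater exon-union length had higher log2 ratios. The length was solved from reads and RPKM, and the length of the transcripts present in the cells was not measured. Across genes, which are not independent replicates, Spearman's rho was 0.22 over 10721 genes without the ribosomal protein, histone and mitochondrial lists, and the decile medians ran from −0.03 for the shortest to 0.26 for the longest. At a mean of at least 5 RPKM rho was 0.30 over 5833 genes, and GC content had a rho of 0.22 over 10134 genes. Exon-union length across all genes may therefore add to small list differences. With random lists matched on this length, 26 of 27 lists kept their side of the percentile limits, S phase being the exception at 98.5.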
